A study of Mus musculus with 4 samples.

How the data were processed

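Cells of the subdural meninges of the cerebellum were measured in 4 libraries by droplet single-cell RNA sequencing (10x Genomics Chromium 3' chemistry), which counts 1 tag near the 3' end of each captured transcript. All mice carried the Neurod2-SmoA1 transgene on 1 allele, on a C57BL/6 background. NdpWT replicates 1 and 2 were wild type for Ndp and NdpKO replicates 1 and 2 were Ndp knockouts. Each library is, per the labels, a pool of 5 cerebella from 3 litters, collected in 4 separate runs in which each wild-type run was matched by litter to a knockout run. The labels do not say that the replicate number marks this match, so the number was not used as a block in the main test. The labels disagree on age: days 6 to 8 after birth in the sample fields and days 7 to 9 in the protocol. Dura and choroid plexus were left aside at dissection, tissue was digested with Dispase II, and cells were spun through 22% Percoll, a density step that removes debris and can favour some cell types.

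The deposited values are UMI counts per gene and barcode in 1 sparse matrix per library, made by the authors with Cell Ranger 6.1.2 and the mm10 genome, per the submitters' processing notes, and not normalised. The matrices hold 32285 features, of which 32158 matched a gene of GENCODE M21 (GRCm38, the same assembly as mm10) by identifier, 31379 of them with the same symbol. Positions are 1-based and come from that annotation. The lowest barcode of every library has 500 UMIs. Whether the authors removed doublets or free RNA is not given in the sources used here, and no correction for free RNA was made. Paralogous genes with shared 3' ends can share tags.

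Barcodes were kept with at least 500 genes, at least 1000 UMIs and at most 10% mitochondrial UMIs, which left 9320, 12818, 5696 and 10888 barcodes in NdpWT replicates 1 and 2 and NdpKO replicates 1 and 2. Scrublet, as in scanpy 1.11.5, was run per library with its automatic threshold and an expected rate of 0.8% per 1000 barcodes, and its 247, 301, 111 and 316 calls were removed. These were 2.65%, 2.35%, 1.95% and 2.90% of the barcodes, below the 11.5%, 15.3%, 10.3% and 13.2% that the loading would give, so doublets remain. Counts per cell were scaled to 10000, log-transformed and reduced to 2000 variable genes and 30 principal components, with no correction between libraries. A graph of 20 shared neighbours (scikit-learn 1.9.0) was clustered by Leiden at resolution 1 (leidenalg 0.10.2, igraph 0.11.9). A cluster took the name of a cell type where at least 3 of its fixed markers were among the 50 genes of highest fold and no other type had more among the first 10. The remaining clusters stayed unnamed, those led by histone and cell cycle genes as a class of cycling cells. Cell class names were rebuilt here and can differ from those of the authors.

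UMI counts were summed per library and class, for the 9 classes with at least 50 cells in every library, since cells are not replicates. Knockout was compared with wild type by edgeR 4.0.16 (quasi-likelihood test, robust, TMM factors, genes kept by filterByExpr with a minimum count of 10) in R 4.3.3, with Benjamini-Hochberg adjustment within each class and a threshold of 0.05. Log2 changes are knockout over wild type, and their standard errors (SE) come from the quasi-likelihood F. CPM of a class use these TMM factors, while sums of markers and the Ndp levels over all cells use plain totals. Shares of cells were tested with edgeR on the number of cells per class and library, with library totals as offset. P-values rest on 2 libraries per genotype, each a pool of separate animals. Counts of different pairs of libraries differed far beyond sampling noise (chi-square per degree of freedom of 106 to 237), so all 4 were counted as separate libraries.

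In all, 27 gene lists were set up, of which a list was tested in a class where at least 5 members were tested. The list of sex-linked genes reached that number in no class. It served as a check: Xist had 6, 11, 12 and 10 UMIs and Ddx3y 65.1, 68.0, 73.5 and 67.4 CPM in NdpWT replicates 1 and 2 and NdpKO replicates 1 and 2. The lists share some members, such as Slc38a5 and Ackr1. Camera (limma 3.58.1) asks whether a list moves further than the other genes, here with a preset correlation between genes of 0.01. With an estimated correlation 0 lists were called in any class, and in simulated counts with 1 list lowered 1.5-fold the preset correlation found it in 9 of 9 classes and the estimated one in 0 of 9. The preset correlation also called 1 list in 3 of 9 classes with nothing changed, and 1 other list in 1 class beside the lowered one. Genes were drawn independently in these counts, so they cannot show how the preset correlation does where genes of a list vary together. The medians and means of the called lists have the sign of the test. Fry asks whether a list's genes move on balance one way, and its mixed p whether they change in either direction, without comparing them with other genes.

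Genes named in the text were picked by rule: for each class and direction up to 12 genes with the largest log2 change among those with an adjusted p under 0.05, a mean of at least 20 CPM and both libraries of a genotype above both of the other. Where fewer than 5 qualified, the genes of lowest p filled up to 5 and are given as values. The 4 members with the lowest p of each called list in its direction, and a fixed panel around norrin, Wnt and Hedgehog signalling, were added. Hmox1 and Ptgds in endothelial cells, Marco and Tnfaip2 in macrophages and Thrsp in cycling cells lie outside the rule and were chosen after their values were seen. Some of the genes so picked are not reported here. The groups, tests, lists, markers, the rule for named genes and most alternatives were fixed before the data were examined. How clusters were scored by these markers was set after the cells had been clustered. A stronger doublet filter, fits of single clusters and tests between classes were chosen after seeing the data.

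The test was run on simulated counts drawn from the means, depths and spread of each class, with 200 genes changed. In endothelial cells (12349 genes) 32.8% of genes changed 1.5-fold, 91.0% changed 2-fold and 100% changed 4-fold were called, in macrophages (12201 genes) 22.4%, 91.0% and 95.5%, in mural cells (10558 genes) 19.4%, 74.6% and 97.0%, and in erythroid cells (9533 genes) 0%, 19.4% and 100%. Of the endothelial calls 18 of 167 (10.8%) were false, of the macrophage calls 10.3% and of the mural calls 16.4%, all above the nominal level. With nothing changed, 3, 18 and 7 genes were called in these classes, against 293, 13 and 4 in the measured counts.

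The alternatives were DESeq2 1.42.0 (Wald test), DESeq2 size factors in edgeR, no filter on low counts, counts thinned to the smallest library, equal numbers of cells, no doublet removal, a stricter cell filter (1000 genes, 2000 UMIs and 5% mitochondrial UMIs), Leiden resolution 2, values centred within each library, a block for the replicate number, each library left out in turn, other totals for the shares, and fry or an estimated correlation for the lists. With 1 library left out, the lone library of a genotype is assumed to vary like the other genotype. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.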

Results

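Single-cell RNA sequencing was carried out on cells peeled from the subdural meninges, the leptomeningeal layer on the surface of the cerebellum, of young mice that carried the Neurod2-SmoA1 transgene on 1 allele. SmoA1 is an activated form of Smoothened, the transducer of Hedgehog signals, and its expression in granule neurons gives cerebellar tumours. The mice were either wild type for Ndp (NdpWT) or Ndp knockout (NdpKO). Ndp encodes norrin, a secreted ligand of the receptor Fzd4 with the co-receptors Lrp5 and Lrp6 and the auxiliary protein Tspan12, which drives Wnt/beta-catenin signalling in endothelial cells of the brain and retina. The comparison addresses how the cells of the meninges next to this cerebellum differ when norrin is missing. Each genotype was measured in 2 libraries, each from a pool of 5 cerebella. The libraries NdpWT replicates 1 and 2 and NdpKO replicates 1 and 2 held 114363848, 121735724, 123270687 and 125981161 UMIs (unique molecular identifiers, 1 per captured transcript) in 14384, 19134, 12904 and 16503 barcodes. After filtering, 9073, 12517, 5585 and 10572 cells remained, with median depths of 9464, 7217, 14272 and 8480 UMIs. NdpKO replicate 1 stood apart from the other 3 libraries: 44.1% of its barcodes passed the cell filter, against 64.8%, 67.0% and 66.0% in NdpWT replicate 1, NdpWT replicate 2 and NdpKO replicate 2, and 21.8% of its barcodes had over 10% mitochondrial UMIs, against 10.4%, 7.60% and 7.58%. With 2 libraries per genotype the smallest 2-sided p of an exact permutation test is 0.333, so tests across all genes or classes were used.

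Ndp itself was lower in both knockout libraries. Ndp (ENSMUSG00000040138, chromosome X, 16885521 to 16911774 on the minus strand, GRCm38) reached 2.07 and 1.36 CPM (UMIs scaled to a common total per library) in the kept cells of NdpWT replicates 1 and 2, with exact 95% Poisson intervals of 1.79 to 2.38 and 1.14 to 1.61. In NdpKO replicates 1 and 2 it stood at 0.413 (0.295 to 0.562) and 0.468 CPM (0.346 to 0.619), so no interval of a knockout library reached that of a wild-type library. These levels rest on 200, 138, 40 and 49 UMIs, and the intervals cover counting error only. The labels do not give the deleted part of the allele. The gene has 3 exons, of which the last (16885521 to 16886696) is 3' untranslated from 16885521 to 16886471, where 3' tags fall, so the remaining tags check the genotype only in part. In the granule neuron lineage, Ndp was at 3.41 and 2.68 CPM in wild-type and 0.856 and 0.699 CPM in knockout cells (log2 change −1.99 ± 0.42 SE, adjusted p = 1). Astroglial cells had the highest wild-type level, 19.3 and 22.5 CPM, against 0 UMIs in NdpKO replicate 1, where a count of 0 allows up to 7.05 CPM, and 2.84 CPM in NdpKO replicate 2. Smo, which includes the transgene if its tags are shared, was at 43.5 and 57.5 CPM in wild-type and 55.4 and 55.6 CPM in knockout libraries.

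Fibroblasts, cells of the granule neuron lineage, macrophages and endothelial cells were the main named cells of the preparation, and no class changed its share with genotype by the test used. The cells fell into 16 classes, of which 14 were named for the cell type whose fixed markers they carried (fibroblast-like, endothelial-like and so on, hereafter without the suffix) and the other 2 were an unnamed class and a class of cycling cells with no cell type name. Fibroblasts made up 19.8 ± 2.60% of wild-type and 28.1 ± 5.32% of knockout cells (mean ± SD, n = 2 each), a log2 change of 0.50 with an adjusted p of 0.965. With the stricter cell filter these shares were 19.2 ± 4.01% and 19.7 ± 1.80%, a log2 change of 0.036. The granule neuron lineage held 32.9 ± 5.71% and 29.6 ± 7.80%, macrophages 9.78 ± 3.78% and 7.99 ± 4.22%, and endothelial cells 5.75 ± 3.91% and 5.17 ± 0.560%. Monocytes or dendritic cells made up 0.964 ± 0.117% of wild-type and 1.91 ± 0.0224% of knockout cells, a log2 change of 0.99 ± 0.47 SE that had the lowest p of all classes (unadjusted p = 0.0731, adjusted p = 0.855). In all, edgeR called 0 of 16 classes, and 0 had an unadjusted p under 0.05. In 3 classes both knockout libraries lay outside both wild-type libraries, where chance gives 33.3% of classes. Without NdpWT replicate 2, the shares of astroglia (adjusted p = 0.0282) and oligodendrocytes (adjusted p = 0.0369) passed the threshold. NdpWT replicate 1 held 1.52% of astroglia and 2.03% of oligodendrocytes, and the other 3 libraries 0.312 to 0.394% and 0.454 to 0.752%. The shares varied by 42.0% between libraries of a genotype, and in simulated data a 2-fold lower macrophage share was called in 4 of 50 draws, a 4-fold lower one in 13 and an 8-fold lower one in 39.

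**Figure D1:**
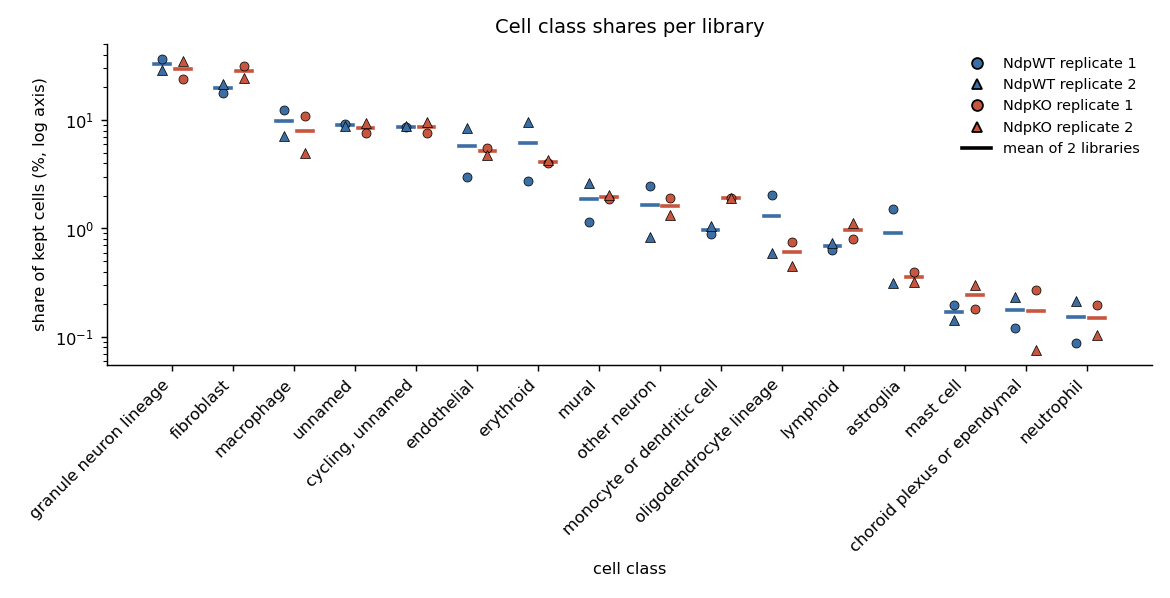
Share of kept cells (percent) in each cell class, with 1 point per library and a bar at the mean of each genotype (n = 2). Fibroblasts stand at 18.0% and 21.6% in the wild-type and 31.8% and 24.3% in the knockout libraries, and the libraries of a genotype lie as far apart as the genotypes in most classes.

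Endothelial cells were the class with the most changed genes when all 4 libraries were used. UMI counts were summed per library within each class, and 9 classes had enough cells for a test. In endothelial cells 123 genes rose and 170 fell in the knockout among 12548 tested. In macrophages 10 rose and 3 fell, in mural cells 2 rose and 2 fell, in cycling cells 1 fell and in the class of other neurons 1 rose. In fibroblasts, the granule neuron lineage, monocytes or dendritic cells and erythroid cells edgeR called 0 genes, and DESeq2 called 52, 1, 13 and 0. Of the 16230, 15133, 8915 and 9827 genes tested there, 929, 193, 533 and 145 had an unadjusted p under 0.05. Chance gives a share of 0.05. The granule neuron lineage and erythroid cells lay below that share, and fibroblasts and monocytes or dendritic cells a little above it. Fibroblasts had more cells than endothelial cells in every library, and in simulated counts 86.6% of genes changed 2-fold were called in fibroblasts and 91.0% in endothelial cells. Leaving out 1 library moved these counts, to between 191 and 491 in endothelial cells, 0 and 518 in the granule neuron lineage, 0 and 190 in cycling cells, 11 and 199 in monocytes or dendritic cells, 1 and 84 in macrophages and 6 and 270 in mural cells. The granule neuron lineage then had more changed genes than endothelial cells without NdpWT replicate 1 (518 against 313) and without NdpWT replicate 2 (257 against 191). With the replicate number as a block, which the labels do not tie to shared litters, 668 genes were called in endothelial cells, 340 in fibroblasts, 188 in monocytes or dendritic cells, 95 in macrophages, 68 in mural cells, 99 in cycling cells and 98 in other neurons, and 0 in the granule neuron lineage and erythroid cells.

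**Figure D2:**
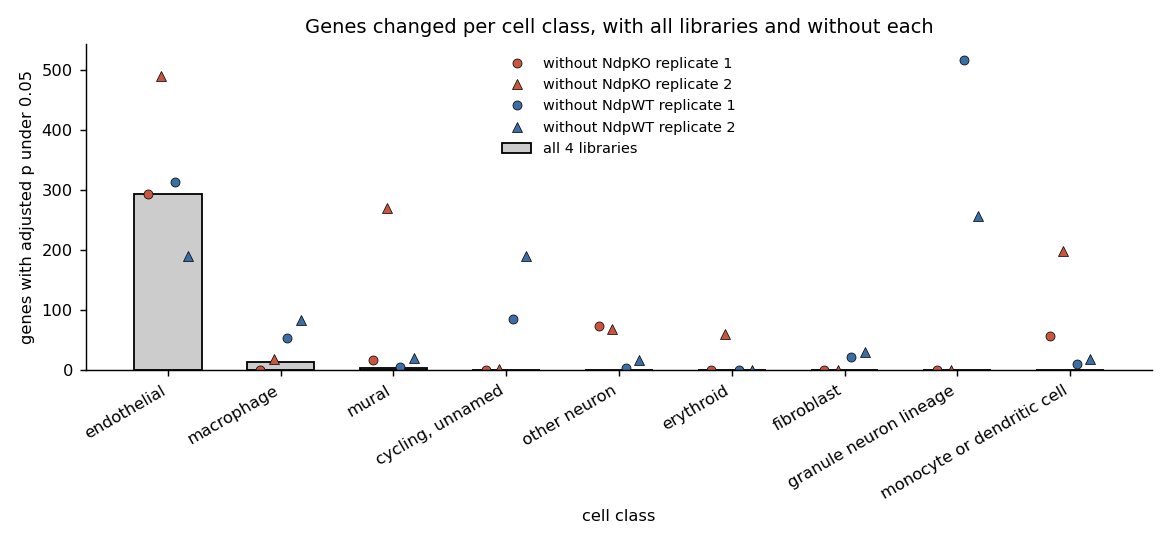
Number of genes called higher or lower in knockout cells of each class (edgeR, adjusted p under 0.05, n = 2 libraries per genotype). Endothelial cells hold 293 of the calls, and macrophages, the next class, 13.

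In endothelial cells of the knockout 13 of 29 blood-brain barrier genes and 5 of 15 Wnt and norrin target genes fell, and 3 of 14 genes of peripheral and activated endothelium rose and 1 fell. All 3 lists were called with a preset correlation between genes, and none with an estimated one (adjusted p of 0.287, 0.312 and 0.287). Plvap, the diaphragm protein of fenestrated capillaries (ENSMUSG00000034845, chromosome 8, 71497765 to 71511752), rose from 14.7 and 18.3 CPM to 78.4 and 104 CPM, a log2 change of 2.43 ± 0.19 SE (adjusted p = 9.69e-05). Slc22a8, an organic anion transporter (ENSMUSG00000063796, chromosome 19, 8591254 to 8611835), fell from 167 and 146 CPM to 33.1 and 29.9 CPM (−2.31 ± 0.15, adjusted p = 3.83e-05). The Wnt feedback genes Apcdd1 (ENSMUSG00000071847, chromosome 18, 62922231 to 62961179) and Nkd1 (ENSMUSG00000031661, chromosome 8, 88521354 to 88594884) fell by 1.64 and 1.63 on the log2 scale, with adjusted p of 0.000153 and 0.000322. Among the genes that rose furthest were also Fam167b (2.65 ± 0.20, chromosome 4, 129576815 to 129578549), the mechanosensitive channel Piezo2 (2.24), the protocadherin Pcdh17 (2.05 ± 0.15) and the transcription factor Irx3 (1.74). Gask1b, Cdh13, Ifi203, Nnat (higher in knockout fibroblasts, whose RNA may add), Plpp3, Tcim and Iigp1 rose by log2 1.65, 1.61, 1.58, 1.46, 1.42, 1.40 and 1.36. Ccdc141 (ENSMUSG00000044033, chromosome 2, 77009902 to 77170636) had the lowest p of the class, with a log2 change of −2.78 ± 0.15 and an adjusted p of 1.32e-05. The monocarboxylate transporter Slc16a1 (−2.24), the thyroid hormone transporter Slco1c1 (−2.08), the transferrin receptor Tfrc (−2.20) and the lipoprotein receptor Lrp8 (−2.03) fell as well. Ly75, Adgrl3, Gsta4 and the non-coding Gm17167 fell by 2.53, 2.28, 2.00 and 2.94 on the log2 scale. Rgs5, a marker of pericytes, fell by 2.90 on the log2 scale in endothelial cells, where the summed mural markers went from 206 and 252 CPM to 155 and 181 CPM. Of the norrin receptor complex, Fzd4 (log2 0.34, adjusted p = 0.267), Lrp5 (0.86, 0.210), Lrp6 (−0.18, 0.694) and Tspan12 (0.15, 0.829) did not pass the test, nor did the tight junction gene Cldn5 (−0.14, 0.866) or the lipid transporter Mfsd2a (−1.71 ± 0.37, 0.159). Cldn5 stood at 0.13 and Tspan12 at −0.08 without NdpWT replicate 2. DESeq2 called 279 genes, and edgeR 313, 191, 294 and 491 without NdpWT replicate 1, NdpWT replicate 2, NdpKO replicate 1 and NdpKO replicate 2. Of the 293 calls, 237, 150, 214 and 256 were kept without NdpWT replicate 1, NdpWT replicate 2, NdpKO replicate 1 and NdpKO replicate 2, and Nnat was lost without NdpWT replicate 2 (adjusted p = 0.0561).

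**Figure D3:**
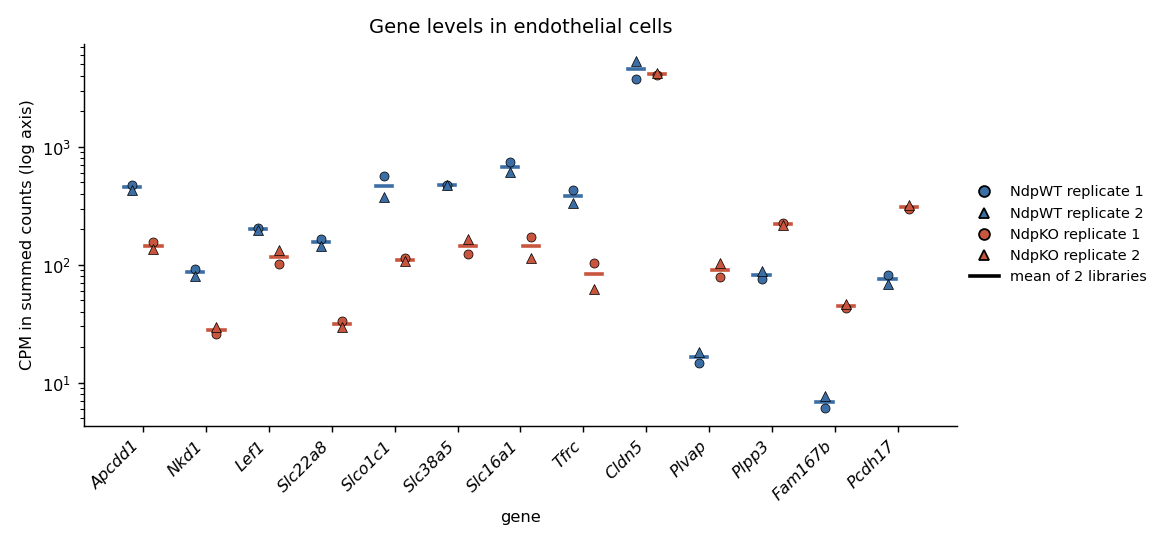
Level (CPM, log axis) of named genes in endothelial cells, 1 point per library. Plvap stands at 14.7 and 18.3 CPM in the wild-type and 78.4 and 104 CPM in the knockout libraries, and Slc22a8 at 167 and 146 against 33.1 and 29.9 CPM.

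Gene lists fixed before the data were examined described these endothelial changes by group. Of 29 measured blood-brain barrier genes 13 fell, 0 rose and 16 did not pass, and 19 fell when adjusted over the list alone. Slc38a5, a glutamine transporter, fell from 478 and 475 CPM to 124 and 165 CPM, and Slc40a1, the iron exporter ferroportin, from 294 and 236 CPM to 87.9 and 70.8 CPM. The median log2 change of the list was −0.71, with an adjusted p of 4.25e-45 by camera, and an adjusted p = 0.287 with an estimated correlation. Of 15 Wnt and norrin target genes 5 fell (Apcdd1, Nkd1, Sp5 by 1.29, Tcf7 by 0.87 and Lef1 by 0.77 on the log2 scale), and 7 fell and 1 rose when adjusted over the list alone, while Axin2 was at −0.90 (adjusted p = 0.0512). Camera gave this list an adjusted p of 3.97e-09, and an adjusted p = 0.312 with an estimated correlation. Of 14 genes of peripheral and activated endothelium 12 were higher, 3 rose and 1 fell (5 and 1 adjusted over the list alone), with an adjusted p of 2.72e-08 and an adjusted p = 0.287 with an estimated correlation. Beside Plvap, Exoc3l2 rose from 0.319 and 1.27 CPM to 14.4 and 12.4 CPM, and Ackr1, the chemokine receptor of venules that the list shares with that of venous genes, fell from 15.3 and 17.3 CPM to 4.09 and 4.51 CPM. All 14 arterial genes were higher and 2 rose, Gja5 by 0.77 and Mgp by 0.79, with 9 adjusted over the list alone (adjusted p = 1.12e-07, and adjusted p = 0.312 with an estimated correlation). Of 12 venous genes 7 were lower, 2 fell and 4 fell when adjusted over the list alone (adjusted p = 0.000154, and adjusted p = 0.424 with an estimated correlation). The endothelial clusters did not have the same weight in all libraries: cluster 13, led by Cldn5, Clec14a and Kdr, held 52.0%, 50.5% and 48.7% of endothelial cells in NdpWT replicates 1 and 2 and NdpKO replicate 2 and 37.6% in NdpKO replicate 1, and cluster 17, led by Eln, Fbln5 and Vwf, 25.1%, 29.1%, 34.9% and 44.7%. Without NdpWT replicate 2, Sp5, Tcf7, Lef1, Gja5 and Mgp had adjusted p of 0.0711, 0.0814, 0.0801, 0.0807 and 0.0807. Without NdpKO replicate 1, Tcf7, Lef1, Gja5 and Mgp had 0.0557, 0.0984, 0.0885 and 0.0966, and without NdpWT replicate 1 Mgp had 0.0705.

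**Figure D4:**
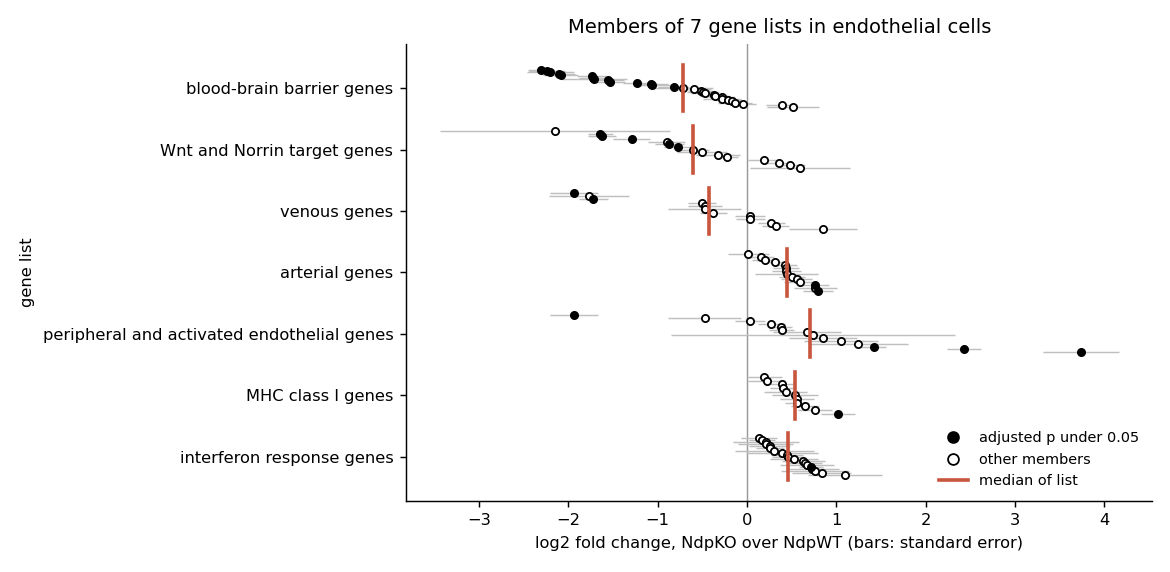
Log2 change (knockout over wild type) of the measured members of gene lists in endothelial cells, 1 point per gene and a bar at the median. The median is −0.71 for blood-brain barrier genes, −0.60 for Wnt and norrin target genes and 0.44 for arterial genes.

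Matrix, MHC class I and interferon genes were on balance higher in knockout endothelial cells, while the list of MHC class II genes was not called. Of 32 extracellular matrix genes 29 were higher, 1 rose (Fbn1, fibrillin, by 0.87) and 1 fell, or 10 and 1 adjusted over the list alone, while Col4a1 was at 0.56 (adjusted p = 0.0919). Camera gave an adjusted p of 1.27e-07, and an adjusted p = 0.548 with an estimated correlation. Summed fibroblast markers, with Mgp, rose here too, from 3637 and 4437 to 8408 and 6540 CPM (log2 0.89 ± 0.23 SE). All 11 MHC class I genes were higher, of which H2-Q7 rose by 1.02 and 7 rose when adjusted over the list alone, and H2-K1 was at 0.56 (adjusted p = 0.0555) and B2m at 0.65 (adjusted p = 0.0648). The adjusted p of the list was 4.03e-07, and adjusted p = 0.287 with an estimated correlation. All 19 interferon response genes were higher, 1 rose (Bst2, tetherin, by 0.71) and 2 rose when adjusted over the list alone (adjusted p = 2.41e-06, and adjusted p = 0.542 with an estimated correlation). Of 23 secreted growth factors 2 rose, Vegfa by 0.99 and Bmp6 by 1.23, and 5 rose and 2 fell when adjusted over the list alone (adjusted p = 0.000154, and adjusted p = 0.381 with an estimated correlation). Of 14 tip cell genes 1 rose, Trp53i11 by 0.70, and 1 fell, or 6 and 1 adjusted over the list alone, and Unc5b was at 0.64 with an adjusted p of 0.0515. The list had an adjusted p of 0.00336, and an adjusted p = 0.334 with an estimated correlation. Of 24 dissociation stress genes 19 were higher and 0 rose, with 1 adjusted over the list alone (Hspa1a 0.78, adjusted p = 0.0617; list adjusted p = 0.00228, and adjusted p = 0.548 with an estimated correlation), a call that was lost without NdpKO replicate 2 (adjusted p = 0.369). The retinoic acid and TGF-beta response lists had 7 of 10 and 11 of 15 genes higher, 0 passed and 1 each rose when adjusted over the list alone, and were called with adjusted p of 0.0295 and 0.0319, and adjusted p = 0.548 and 0.424 with an estimated correlation. Retinoic acid genes were lost without NdpWT replicate 1 (0.369) or NdpKO replicate 1 (0.122), and TGF-beta response genes without NdpWT replicate 1 (0.369) or NdpKO replicate 2 (0.354). The 23 hypoxia and glycolysis genes, of which 3 rose and 4 rose when adjusted over the list alone, were not called as a list (adjusted p = 0.0683) and were the only tested list called in no class. Fbn1, H2-Q7, Bst2, Vegfa, Bmp6 and Trp53i11 had adjusted p of 0.0645, 0.0612, 0.0667, 0.0853, 0.0937 and 0.104 without NdpWT replicate 2. Vegfa, Bmp6 and Trp53i11 had 0.0711, 0.176 and 0.0806 without NdpKO replicate 1, and Bmp6 had 0.0845 without NdpWT replicate 1. In all classes together, 0 lists kept a call with an estimated correlation, including the lists changed on purpose in simulated counts of all 9 classes. Genes of those simulated counts were drawn independently.

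Hmox1, Slc48a1 and Slc40a1, whose products degrade haem, carry haem and export iron, rose in knockout macrophages. Hmox1, haem oxygenase (ENSMUSG00000005413, chromosome 8, 75093621 to 75100589), rose from 348 and 527 CPM to 1440 and 1143 CPM (log2 1.56 ± 0.21 SE, adjusted p = 0.0390). Slc48a1, a haem transporter of phagolysosomes, rose from 55.3 and 77.7 CPM to 167 and 147 CPM (1.25), and Slc40a1, ferroportin (ENSMUSG00000025993, chromosome 1, 45908068 to 45926523), from 304 and 377 CPM to 849 and 647 CPM (1.14 ± 0.17). Tfrc, the transferrin receptor (ENSMUSG00000022797, chromosome 16, 32608920 to 32632794), fell from 62.8 and 57.1 CPM to 31.5 and 28.0 CPM (adjusted p = 0.0390). The glutathione transferases Mgst1 and Gstm1 rose by 1.40 and 0.97, the aldo-keto reductase Akr1b8 by 1.29, Cela1 by 1.55 and Ly6e by 0.84. Marco, a scavenger receptor, and Tnfaip2 rose by 2.78 and 1.44 and were named after their values were seen, as both lie under the CPM minimum for named genes. Slc38a5 fell from 3.36 and 5.59 CPM to 0.115 and 0.395 CPM. Mbp, a myelin gene, fell by 1.35 on the log2 scale, and the summed oligodendrocyte markers in macrophages went from 125 and 95.5 CPM to 65.3 and 55.6 CPM. Igf1 (355 and 392 against 644 and 645 CPM, adjusted p = 0.0634), Hist1h1b (−0.88, 0.0619), Spp1 (−0.83, 0.216) and Pclaf (−0.65, 0.267) did not pass the test. Of the 13 calls, 13, 13, 0 and 8 were kept without NdpWT replicate 1, NdpWT replicate 2, NdpKO replicate 1 and NdpKO replicate 2, and the counts of changed genes were then 54, 84, 1 and 18. Without NdpKO replicate 1, Hmox1 was at log2 1.38 with an adjusted p of 0.364, Slc48a1 at 1.15 with 0.364 and Slc40a1 at 0.92 with 0.563. Without NdpKO replicate 2 the calls of Cela1, Ly6e, Tnfaip2, Tfrc and Slc38a5 were lost (adjusted p of 0.195, 0.272, 0.151, 0.161 and 0.0645). DESeq2 called 23 genes in this class. EdgeR called 2 with the stricter cell filter, 2 with values centred within libraries, 7 with no doublet removal and 7 with equal numbers of cells. It called 18 in simulated macrophage counts with no change.

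**Figure D5:**
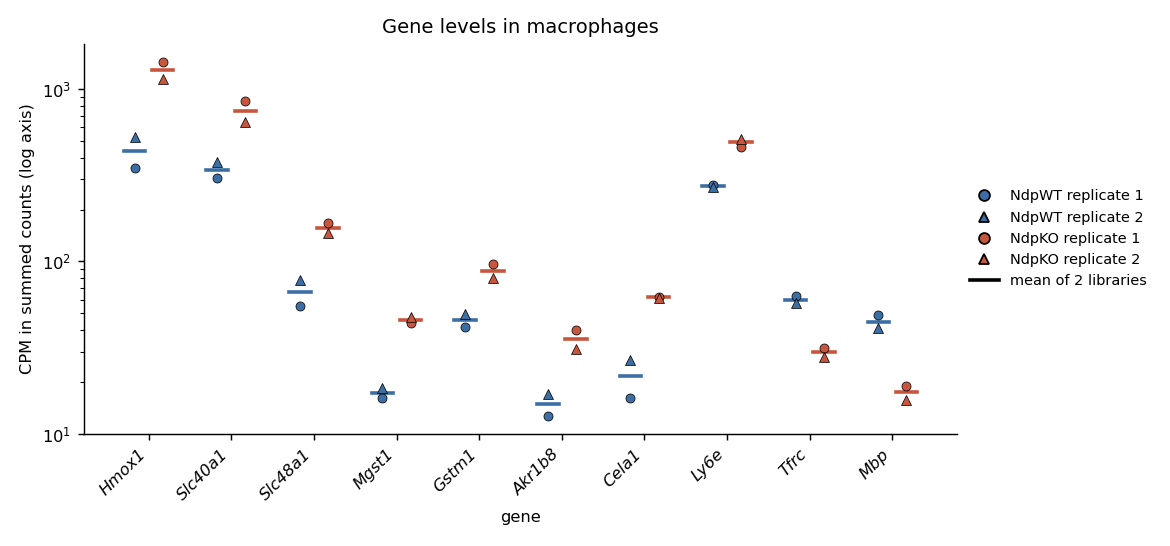
Level (CPM, log axis) of named genes in macrophages, 1 point per library. Hmox1 stands at 348 and 527 CPM in the wild-type and 1440 and 1143 CPM in the knockout libraries, and Tfrc at 62.8 and 57.1 against 31.5 and 28.0 CPM.

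MHC class I genes were higher and cell cycle genes lower in knockout macrophages as lists, while the list of MHC class II genes was not called. All 12 MHC class I genes were higher, 0 rose and 7 rose when adjusted over the list alone (H2-K1 at 0.62 and B2m at 0.71), with an adjusted p of 5.38e-11, and an adjusted p = 0.746 with an estimated correlation. Of 20 interferon response genes 18 were higher, 0 passed and 4 rose and 1 fell when adjusted over the list alone (Oasl2 at 0.82 and Rtp4 at 0.48, list adjusted p = 1.89e-05). Of 32 cell cycle genes 28 were lower and 0 fell, Top2a being at −0.46 (adjusted p = 3.66e-06). Of 23 blood-brain barrier genes 19 were lower, 1 rose (Slc40a1) and 2 fell (Tfrc and Slc38a5), or 1 and 5 adjusted over the list alone (adjusted p = 3.21e-06). Slc38a5 fell in endothelial cells too, whose summed markers stood in macrophages at 428 and 483 CPM in wild-type and 396 and 449 CPM in knockout libraries. These 4 lists kept their calls without each library in turn and had an adjusted p = 0.746 with an estimated correlation. The other 7 of the 11 called lists also had an adjusted p = 0.746 with an estimated correlation, and each lost its call or turned without a library. Dissociation stress genes, 20 of 24 lower (Ier2 at −0.63 and Jund at −0.55, list adjusted p = 0.000116), had 0.745 without NdpWT replicate 1. Border macrophage genes, 15 of 19 higher (Cd163 at 0.30, list adjusted p = 0.0453), had 0.967 without NdpWT replicate 2 and 0.275 without NdpKO replicate 1. Lipid and phagocytosis genes, 12 of 17 higher, had 0.0318 in all libraries, 0.0671 without NdpWT replicate 1 and 0.551 without NdpKO replicate 2. Oxidative phosphorylation genes, 26 of 32 higher, had 0.0351, and 0.997 without NdpWT replicate 2 and 0.275 without NdpKO replicate 1. Hedgehog pathway genes, 11 of 12 lower, had 0.0107, and 0.997 with the opposite direction without NdpWT replicate 2 and 0.0501 without NdpKO replicate 1. Granule cell progenitor genes, 10 of 11 lower, had 0.00411, and 0.997 without NdpWT replicate 2, and granule cell differentiation genes, 12 of 13 lower, had 0.0407, and 0.381 without NdpWT replicate 1 and 0.823 with the opposite direction without NdpKO replicate 1.

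Mural cells of the knockout had more Eln and less Ifitm1. Eln, elastin (ENSMUSG00000029675, chromosome 5, 134702593 to 134747323), rose from 1225 and 1485 CPM to 3508 and 2744 CPM (log2 1.20 ± 0.16 SE, adjusted p = 0.0246), and Crispld2, a secreted matrix protein, from 107 and 156 CPM to 308 and 314 CPM. Ifitm1, an interferon-induced membrane protein (ENSMUSG00000025491, chromosome 7, 140967221 to 140969825), fell from 214 and 200 CPM to 65.3 and 86.2 CPM (−1.44 ± 0.16, adjusted p = 0.0115). The contractile gene Cnn1 (0.85, adjusted p = 0.0822), Id1 (0.79, 0.121) and Mustn1 (0.73, 0.126) did not pass the test, nor did Pltp (−1.05, 0.0638) or Rap2a (−0.76, 0.121). Of 10 retinoic acid pathway genes 8 were lower and 0 passed, with 4 lower and 1 higher when adjusted over the list alone (Aldh1a2 at −1.38), and the list had an adjusted p of 0.000101, and an adjusted p = 0.423 with an estimated correlation. Of 24 dissociation stress genes 21 were higher (Atf3 at 0.53), with the same pair of adjusted p. Aldh1a2 is also a fibroblast marker. Of 11 Wnt and norrin target genes 7 were lower, 3 of them and 1 higher gene passing when adjusted over the list alone (Axin2 at −1.03, Lef1 at −2.00 and Tnfrsf19 at −0.59). This list had an adjusted p of 0.0202, an adjusted p = 0.551 with an estimated correlation, and 0.101 without NdpKO replicate 2. TGF-beta response genes, 10 of 15 higher and 5 higher and 1 lower when adjusted over the list alone (Acta2 at 0.44), had an adjusted p of 0.0273, an adjusted p = 0.551 with an estimated correlation, and 0.0528, 0.110, 0.0711 and 0.253 without NdpWT replicate 1, NdpWT replicate 2, NdpKO replicate 1 and NdpKO replicate 2. It was the only list of any class that fry called (adjusted p = 0.0274). The other called lists were granule cell differentiation genes (11 of 11 lower), blood-brain barrier genes (16 of 20 lower), oxidative phosphorylation genes (29 of 32 higher), haemoglobin and erythroid genes (5 of 6 higher), mitochondrially encoded genes (11 of 13 higher) and cell cycle genes (23 of 32 higher), with adjusted p of 0.000322 to 0.0351, and adjusted p = 0.423 to 0.616 with an estimated correlation. In mural cells the summed endothelial markers went from 648 and 779 CPM to 524 and 536 CPM. Those of the granule lineage, other neurons and erythroid cells changed by −0.86 ± 0.91, −1.69 ± 0.96 and 0.64 ± 0.82 on the log2 scale, each within 2 SE of 0. Without NdpKO replicate 1 granule cell differentiation, oxidative phosphorylation and mitochondrially encoded genes had adjusted p of 0.158, 0.158 and 0.521. Without NdpWT replicate 2 blood-brain barrier, oxidative phosphorylation and mitochondrially encoded genes had 0.0527, 0.182 and 0.160. Haemoglobin and cell cycle genes had 0.430 and 0.804 without NdpWT replicate 1 and 0.264 and 0.827 without NdpKO replicate 2, where cell cycle genes turned. The counts of changed genes were 6, 20, 17 and 270 without NdpWT replicate 1, NdpWT replicate 2, NdpKO replicate 1 and NdpKO replicate 2, with the 4 calls kept each time, and 17 by DESeq2. In simulated mural counts with no change 7 genes were called.

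Fibroblasts had no called gene in the main test and 340 with the replicate number as a block, with matrix and stress genes lower as lists. The imprinted gene Nnat (651 and 509 against 1303 and 1401 CPM), the glutathione transferase Gstm1 (81.4 and 89.9 against 178 and 160 CPM), Arrdc3 (log2 0.95) and Tmem132c (−1.12) had the lowest p, each with an adjusted p of 0.240. Tmem158 stood at 0.75, Gpcpd1 at 0.87, Neat1 at −1.09 and S100a6 at −0.80. Of 32 extracellular matrix genes 24 were lower, 0 passed and 4 fell when adjusted over the list alone, among them the basement membrane collagens Col4a1 (929 and 846 against 541 and 551 CPM) and Col15a1 (−1.24), and Lama1 was at −0.71. The list had an adjusted p of 2.04e-06, and an adjusted p = 0.542 with an estimated correlation. Of 24 dissociation stress genes 22 were lower (Jun at −0.59 and Klf2 at −0.72), with an adjusted p of 4.06e-07, and an adjusted p = 0.542 with an estimated correlation. These lists kept their calls without each library in turn, and the other 10 of the 12 called lists did not. Wnt and norrin target genes, 13 of 18 lower and 2 adjusted over the list alone (Lef1 at −0.78 and Wif1 at −0.72), had an adjusted p of 0.000367, an adjusted p = 0.542 with an estimated correlation, and 0.0706 without NdpWT replicate 2. All 13 mitochondrially encoded genes were higher (mt-Co2 at 0.37), with an adjusted p of 5.89e-06, an adjusted p = 0.603 with an estimated correlation, and 0.0706 without NdpWT replicate 2, and the median mitochondrial share of fibroblasts was 3.93% and 3.31% in wild-type and 5.00% and 4.23% in knockout libraries. The remaining called lists were border macrophage genes (15 of 16 lower), oxidative phosphorylation genes (26 of 32 higher), granule cell differentiation genes (12 of 14 lower), granule cell progenitor genes (9 of 12 lower), MHC class I genes (8 of 11 higher), interferon response genes (16 of 21 lower), venous genes (10 of 11 lower) and TGF-beta response genes (14 of 16 lower). Their adjusted p by camera ranged from 0.000163 to 0.0295, and adjusted p = 0.542 to 0.756 with an estimated correlation. Summed markers of the granule lineage in fibroblasts fell along with its lists, from 508 and 431 CPM to 259 and 353 CPM (log2 −0.62 ± 0.25), and those of other neurons changed by −0.68 ± 0.23. Border macrophage and TGF-beta response genes were lost without NdpWT replicate 1 (0.756 and 0.0897). Without NdpWT replicate 2 oxidative phosphorylation, granule cell progenitor, MHC class I, interferon response, venous and TGF-beta response genes were lost (0.168, 0.155, 0.0706, 0.933, 0.249 and 0.523). Without NdpKO replicate 1 granule cell differentiation, interferon response, venous and TGF-beta response genes had 0.486, 0.928, 0.174 and 0.0880, and without NdpKO replicate 2 granule cell progenitor and MHC class I genes had 0.0572 and 0.272. The count of changed genes was 22 without NdpWT replicate 1, 31 without NdpWT replicate 2 and 0 without either knockout library.

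In monocytes or dendritic cells border macrophage and interferon genes were higher and matrix and cell cycle genes lower as lists, with no gene called in the main test and 188 with the replicate number as a block. The summed markers of other cell types moved in this class too. Macrophage markers went from 3345 and 1874 CPM to 3565 and 4725 CPM (log2 0.67 ± 0.45 SE), and those of microglia, lymphoid and mural cells changed by 0.32 ± 0.08, −1.97 ± 0.70 and −1.55 ± 0.69. Those of fibroblasts, which make matrix genes, went from 3393 and 3551 CPM to 2509 and 3298 CPM (−0.26 ± 0.20). Fcgr1, an IgG receptor of monocytes and macrophages (37.8 and 50.2 against 124 and 113 CPM), Ccl7 (log2 1.44), Maf (1.32), Gpr183 (1.28), P2ry12 (1.46) and the mannose receptor Mrc1 (190 and 174 against 339 and 402 CPM) each had an adjusted p of 0.139, as had the lower Fstl1 (−1.40) and Stmn1 (−0.98). Phlda1 was at −1.34, Cdca8 at −1.29 and Pclaf at −1.01. Of 14 border macrophage genes 11 were higher, 0 passed and 6 rose when adjusted over the list alone (Mrc1, and Pf4 at 1.90), with an adjusted p of 6.09e-12. Of 26 extracellular matrix genes 25 were lower, 7 when adjusted over the list alone (Fbln2 at −2.31 and Col5a1 at −1.69), with an adjusted p of 5.04e-17. Of 31 cell cycle genes 29 were lower (Mki67 at −0.75, list adjusted p = 7.58e-10), and all 19 interferon response genes were higher, 2 when adjusted over the list alone (Bst2 at 0.99, list adjusted p = 3.73e-09). The first 3 of these lists had an adjusted p = 0.511 with an estimated correlation and interferon response genes an adjusted p = 0.604. All 4 kept their calls without each library in turn, and the other 5 of the 9 called lists did not. Granule cell differentiation (7 of 8 lower), growth factor (9 of 14 lower), retinoic acid (5 of 5 lower), MHC class I (9 of 11 higher) and venous genes (5 of 6 lower), called with adjusted p of 0.00157 to 0.0271 and adjusted p = 0.604 to 0.644 with an estimated correlation, had 0.0661, 0.395, 0.351, 0.182 and 0.880 without NdpKO replicate 1. Without NdpWT replicate 1 growth factor, retinoic acid and MHC class I genes had 0.122, 0.273 and 0.273, and without NdpWT replicate 2 granule cell differentiation and venous genes had 0.111 and 0.225. The count of changed genes was 11, 18, 57 and 199 without NdpWT replicate 1, NdpWT replicate 2, NdpKO replicate 1 and NdpKO replicate 2.

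In the class named granule neuron lineage no gene was called, and the Hedgehog targets Gli1 and Ptch1 did not pass the test. The class of cycling cells carried granule lineage markers too, at 4393 and 3126 CPM in wild-type and 4196 and 3760 CPM in knockout libraries. In the granule neuron lineage these stood at 8458 and 5150 against 7390 and 7662 CPM. Dividing cells of this lineage may thus lie in the cycling class, which the values below leave out. Gli1 (11.5 and 23.7 against 21.2 and 12.5 CPM) and Ptch1 (120 and 192 against 161 and 127 CPM) had log2 changes of −0.07 and −0.11, each with an adjusted p of 1. These were 0.53 and 0.26 without NdpWT replicate 2, and without NdpKO replicate 2 they were 0.27 and 0.05. The 15 Hedgehog pathway genes had a median log2 change of −0.02, with camera's direction the opposite one (adjusted p = 0.732). The genes of lowest p were Ostf1 (log2 0.86), Ifi203 (0.74), Tmem181a (0.72), AA465934 (0.86) and Rab15 (0.52) on the higher side. On the lower side they were the platelet factor Pf4 (−0.96), Ntng1 (−0.72), Mab21l2 (−1.70), Tbata (−0.55) and Rmst (−1.02), all with an adjusted p of 1. Of 16 border macrophage genes 14 were lower, 0 passed and 4 fell when adjusted over the list alone (Pf4, Lyve1 at −1.70 and Mrc1 at −0.91), with an adjusted p of 2.59e-22, and 14 of 16 inflammatory and NF-kB genes were lower (Cxcl2 at −1.51, list adjusted p = 4.00e-07), both with an adjusted p = 0.742 with an estimated correlation. The summed macrophage markers in these cells went from 129 and 157 CPM to 70.0 and 81.3 CPM. Both lists kept their calls without each library in turn, and the other 5 of the 7 called lists did not, among them MHC class II genes, 5 of 8 lower (adjusted p = 0.00868, and 0.305 without NdpWT replicate 2 and 0.495 without NdpKO replicate 1). Cholesterol synthesis genes, 14 of 17 lower (adjusted p = 0.00425), had 0.904 and the opposite direction without NdpWT replicate 1 and 0.0802 without NdpKO replicate 1. Blood-brain barrier genes (25 of 29 lower), cell cycle genes (24 of 32 lower) and oxidative phosphorylation genes (25 of 32 higher) turned without NdpWT replicate 2 (0.156, 0.0149 and 0.419), and the last had 0.220 without NdpKO replicate 1. The adjusted p of the last 3 lists by camera in all libraries were 0.00252, 0.00121 and 0.0328, and all 5 had an adjusted p = 0.823 with an estimated correlation. The count of changed genes was 518 without NdpWT replicate 1, 257 without NdpWT replicate 2 and 0 without either knockout library.

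In the class of cycling cells, Thrsp, a lipogenic gene, fell from 11.3 and 15.7 CPM to 4.04 and 2.82 CPM (log2 −2.00 ± 0.27 SE, adjusted p = 0.0334), and was named after its values were seen. Ostf1 (log2 1.01, adjusted p = 0.0991) and Mfap4, a matrix gene and granule lineage marker here (247 and 244 against 418 and 412 CPM, 0.177), did not pass the test. Nor did Bcas1 (−0.99, 0.147), Rab15 (0.67), Rccd1 (0.64) or Fam210b (−0.64). Of 16 border macrophage genes 15 were lower, 9 when adjusted over the list alone (Folr2 at −2.40 and Lyve1 at −1.47 among them, list adjusted p = 9.72e-23, and adjusted p = 0.350 with an estimated correlation). The summed macrophage markers in these cells went from 96.0 and 76.7 CPM to 52.7 and 37.4 CPM. Of 17 cholesterol synthesis genes 15 were lower (adjusted p = 2.73e-06, and adjusted p = 0.729 with an estimated correlation). Summed oligodendrocyte and choroid plexus markers changed by −0.62 ± 0.12 and −0.60 ± 0.08 on the log2 scale in these cells. No summed markers rose there by more than 2 SE. All 5 haemoglobin and erythroid genes were lower, 2 when adjusted over the list alone (adjusted p = 2.02e-07, and adjusted p = 0.729 with an estimated correlation), a call that was lost without NdpKO replicate 2 (0.0660). Apoe was at −0.62. Blood-brain barrier genes (21 of 27 lower, 0.00299) and inflammatory genes (8 of 12 lower, 0.0453) were lost without NdpWT replicate 2 (0.797) and NdpWT replicate 1 (0.964), and in the same order also without NdpKO replicate 1 (0.0974) and NdpKO replicate 2 (0.0660), and had adjusted p = 0.729 with an estimated correlation. Thrsp was lost without NdpKO replicate 1 (adjusted p = 0.223) and NdpKO replicate 2 (0.847), and the count of changed genes was 86, 190, 0 and 2 without NdpWT replicate 1, NdpWT replicate 2, NdpKO replicate 1 and NdpKO replicate 2, and 6 by DESeq2.

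In the other neurons, Mfap4 rose from 19.6 and 15.3 CPM to 57.8 and 81.3 CPM (log2 1.91 ± 0.30 SE, adjusted p = 0.0388), and mitotic genes were lower as a list. This was the only call of the class, and in simulated counts of other neurons with no change 5 genes were called. Mfap4 is also a granule lineage marker here, and the sum of these markers went from 4003 and 4016 CPM to 4650 and 4640 CPM. Of 30 cell cycle genes 29 were lower, 0 passed and 10 fell when adjusted over the list alone (among them Birc5 at 87.3 and 74.5 against 30.1 and 32.5 CPM and Tpx2 at −1.53), with an adjusted p of 1.73e-21, and an adjusted p = 0.595 with an estimated correlation. Outside the list, Nusap1 was at −1.74 and Aspm at −1.62. Of 13 granule cell differentiation genes 9 were higher, 2 when adjusted over the list alone (Cntn2 at 1.44 and Rbfox3 at 0.73), with an adjusted p of 0.00146, an adjusted p = 0.595 with an estimated correlation, and 0.0780 without NdpKO replicate 2. All 5 border macrophage genes were lower, 2 when adjusted over the list alone (Pf4 at −1.77 and Mrc1 at −2.03), as were the summed macrophage markers (111 and 145 against 62.1 and 74.8 CPM), with a list adjusted p of 0.000332, an adjusted p = 0.860 with an estimated correlation, and 0.102 without NdpWT replicate 2. Mfap4 was lost without NdpWT replicate 1 (adjusted p = 0.104). No gene was called with no doublet removal, the stricter cell filter, Leiden resolution 2, values centred within libraries, equal numbers of cells, thinned counts or doublets at the loading rate, under which Mfap4 was at log2 1.23 to 2.22. The count of changed genes was 4, 17, 73 and 69 without NdpWT replicate 1, NdpWT replicate 2, NdpKO replicate 1 and NdpKO replicate 2, and DESeq2 called 0.

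Erythroid cells had no called gene, and the lowest p belonged to Mfap4 (log2 0.82), Lockd (0.95), the interferon-induced gene Isg15 (0.63) and Tlx3 (−0.52), all with an adjusted p of 1. All 32 cell cycle genes were higher (Cdk1 at 0.97, list adjusted p = 1.74e-09, and adjusted p = 0.804 with an estimated correlation). This turned to lower levels without NdpKO replicate 1 (adjusted p = 0.0466). Of 11 border macrophage genes 9 were lower, 1 when adjusted over the list alone (Mrc1 at −1.51, list adjusted p = 4.18e-05, and adjusted p = 0.804 with an estimated correlation), a call that was lost without NdpWT replicate 2 (0.598). Of the 10 called lists of this class 0 kept a call without each library in turn. Dissociation stress (15 of 20 lower), inflammatory (5 of 8 lower), MHC class I (7 of 7 higher), cholesterol synthesis (13 of 17 lower), oxidative phosphorylation (30 of 32 higher) and haemoglobin genes (6 of 7 higher) had adjusted p of 0.381, 0.0671, 0.212, 0.802, 0.381 and 0.381 without NdpKO replicate 1, where haemoglobin genes turned. Retinoic acid genes (7 of 10 higher) and growth factors (16 of 21 higher) had 0.960 and 0.960 without NdpKO replicate 2, where growth factors turned, and 0.762 and 0.0928 without NdpWT replicate 1, where both turned. Without NdpWT replicate 1 MHC class I, cholesterol synthesis and haemoglobin genes had 0.452, 0.563 and 0.208, and without NdpWT replicate 2 haemoglobin, oxidative phosphorylation and stress genes 0.136, 0.574 and 0.388. Without NdpKO replicate 2 MHC class I genes also lost their call, and oxidative phosphorylation and inflammatory genes had 0.118 and 0.164. These 8 lists were called with adjusted p of 0.0213 to 0.0439, and had adjusted p = 0.804 to 0.875 with an estimated correlation. The count of changed genes was 60 without NdpKO replicate 2 and at most 1 without any other library.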

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

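The tests of free macrophage RNA, fewer macrophages, a shift between macrophage clusters, free fibroblast RNA, dilution of endothelial RNA, dissociation stress, haemoglobin uptake and NdpKO replicate 1 as the whole cause, and all tests between classes or clusters, were chosen only after the result was seen.

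The effect of the knockout differed between cell classes for many genes, by a test of the difference itself (interaction of class and genotype, edgeR, adjusted p under 0.05). Between endothelial cells and fibroblasts 324 of 12372 genes differed in their change, between endothelial cells and macrophages 197 of 11392 and between endothelial and mural cells 152 of 10378. Against the granule neuron lineage 0 of 12093 genes differed from endothelial cells by edgeR, with 960 at an unadjusted p under 0.05, and DESeq2 was not run on differences between classes. Macrophages differed from monocytes or dendritic cells in 38 of 8733 genes and from fibroblasts in 4 of 12117. Within endothelial cells, cluster 13 (led by Cldn5, Clec14a and Kdr) and cluster 17 (led by Eln, Fbln5 and Vwf) differed in 144 of 10196 genes. Among the fibroblast clusters, cluster 3 (led by Ptgds, Slc6a13 and Aldh1a2) and cluster 6 (led by Col15a1, Col4a1 and Col3a1) differed in 75 of 12827 genes, clusters 6 and 11 (the latter led by Igfbp6, Mgp and Nppc) in 32 of 12318 and clusters 3 and 11 in 11 of 12992.

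Slc40a1, ferroportin, moved in opposite directions in 2 classes. It fell by 1.73 on the log2 scale in endothelial cells and rose by 1.14 in macrophages, a difference of −2.85 (adjusted p = 0.0118). Hmox1 was at −0.91 ± 0.20 in endothelial cells and 1.56 in macrophages, and this difference did not pass the test (adjusted p = 0.248). The endothelial call of Hmox1 was lost without NdpWT replicate 1 (adjusted p = 0.112) and NdpKO replicate 1 (0.0557), and the macrophage call of Slc40a1 without NdpKO replicate 1 (0.563).

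The first pattern weighed is that of blood-brain barrier genes, lower in knockout endothelial cells with a median log2 change of −0.71. The list was also called lower in macrophages, mural cells, the granule neuron lineage and cycling cells. Of these calls only that in macrophages was kept without each library in turn. A cause shared by these classes was not tested. A smaller part of capillary cells is argued against as the whole cause, since the median within cluster 13 alone was −0.61. Free RNA of granule lineage cells and fibroblasts as the source of these transcripts is argued against, since the members stood there at a median of 0.0224 (quartiles 0.0094 to 0.0913) and 0.0809 (0.0151 to 0.228) of their endothelial level in wild type. Dilution by RNA of other cells is argued against by a median of 0.034 (quartiles −0.19 to 0.32) for the 16 endothelial markers outside the list. The planned test of low quality in NdpKO replicate 1 was undecided: the median without it was −0.53, so a part may come from it. It is argued against as the whole cause, as 26 of 29 members stayed lower with NdpKO replicate 2 alone. The loss of norrin, which the design gives, stays open as the biological explanation, and with it all that differs between pools of 5 cerebella.

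The second pattern is the rise of 10 genes in knockout macrophages, among them Hmox1, Slc48a1 and Slc40a1, with a median log2 change of 1.34. A shift between macrophage clusters is argued against by a median of 1.37 for the same genes within cluster 7 alone. These genes were called in the same cells, however, and cluster 7 is a large part of the class. It held at least 3377360 UMIs per library, against at least 4929243 in the class. A shift of states within cluster 7 was not tested. Free fibroblast RNA is argued against by a median of 0.15 for 25 fibroblast markers (quartiles −0.16 to 0.29), and their sum changed by 0.45 ± 0.33. More dissociation stress in knockout libraries could not be decided: the stress genes of macrophages had a median of −0.33 (quartiles −0.55 to −0.09), but the list turned without NdpWT replicate 1 (adjusted p = 0.745) and was higher in knockout endothelial (adjusted p = 0.00228) and mural cells (0.000101). Uptake of red blood cells by knockout macrophages could not be decided either: haemoglobin UMIs in macrophages relative to granule lineage cells had ratios of 8.10 and 6.02 in wild-type and 9.92 and 3.14 in knockout libraries, a log2 change of −0.11 ± 0.78 SE, and haem can outlast the RNA. Without NdpKO replicate 1 the rise was smaller for Hmox1 (log2 1.38, 1.56 with it) and Slc40a1 (0.92) but not Mgst1 (1.45, 1.40). This library may carry a part. Simulated macrophages with no change gave 18 calls, so chance and a biological difference stay open.

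The third pattern is that of macrophage markers, lower in some of the other classes of the knockout. Their sum changed by −0.92 ± 0.18 SE on the log2 scale in the granule neuron lineage, −0.99 ± 0.28 in erythroid cells, −0.94 ± 0.29 in cycling cells, −0.90 ± 0.24 in other neurons and −0.82 ± 0.36 in mural cells, but −0.03 ± 0.19 in fibroblasts and −0.20 ± 0.27 in endothelial cells. Single markers had a median of −0.56 in fibroblasts (quartiles −0.79 to −0.37) and −0.02 in endothelial cells (−0.12 to 0.15). Free macrophage RNA in the droplets stays open. The changes in granule lineage and erythroid cells differed by 0.0726 ± 0.335, as free RNA predicts, but the macrophage markers in endothelial cells did not fall with them. Their sum stood at 548 and 419 CPM in wild-type endothelial cells and 129 and 157 CPM in wild-type granule lineage cells. A fall of free RNA could thus be masked in endothelial cells. Droplets that hold a granule cell and a macrophage are argued against, since without the 5.91% of granule lineage cells that had at least 3 such UMIs the change was −0.86 ± 0.21. Fewer macrophages among the knockout cells and less RNA lost per macrophage cannot be told apart with 2 libraries per genotype, the change per percent of UMIs from macrophages being −0.37 ± 0.75.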

How the results depend on the processing

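Doublets at the loading rate and the fits of single clusters were chosen only after the result was seen, and all other alternatives were set beforehand. Of 943 comparisons of the 63 called genes named in the text with an alternative, 820 kept direction and call, 123 kept the direction alone and 0 turned. Of 954 comparisons for the 80 called lists in the 9 classes, 632 kept direction and call, 302 kept the direction alone and 20 turned. Of 2844 comparisons over all 191 named genes 9 turned. The alternatives moved the median of all tested genes of a class by at most 0.0534 on the log2 scale, and DESeq2 size factors left the endothelial count at 293 and its share of genes that rose at 42.0% against 42.3%. Under no alternative fitted to the whole class did a called endothelial gene turn, though all of them reuse the same libraries. In simulated counts 40.3% of genes changed 2-fold were called in monocytes or dendritic cells and 41.8% in other neurons. Unless a cause is named, the cause of a change was not tested.

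With the replicate number as a block, the number of changed genes was 99 in cycling cells, 668 in endothelial cells, 340 in fibroblasts, 95 in macrophages, 188 in monocytes or dendritic cells, 68 in mural cells and 98 in other neurons, and 292 of the 293 endothelial calls were kept. The pairing check gave correlations of same-numbered libraries' deviations of 0.0332 to 0.369, with 0.0793 in endothelial cells. The labels do not tie the numbers to shared litters, so the block rests on a number alone. Its log2 changes of shares turned for endothelial cells (0.026) and other neurons (0.14), and the retinoic acid list in endothelial cells had an adjusted p of 0.0536.

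The numbers of changed genes moved over 1.5 times as follows. DESeq2's Wald test called 6 genes in cycling cells, 52 in fibroblasts, 1 in the granule neuron lineage, 23 in macrophages, 13 in monocytes or dendritic cells, 17 in mural cells and 0 in other neurons. With no filter on low counts, which tests more genes, there were 61 in cycling cells, 756 in endothelial cells, 2 in erythroid cells, 27 in fibroblasts, 1 in the granule neuron lineage, 102 in macrophages, 85 in monocytes or dendritic cells, 145 in mural cells and 60 in other neurons. The stricter cell filter gave 2 in fibroblasts, 2 in macrophages, 1 in monocytes or dendritic cells, 16 in mural cells and 0 in other neurons. Values centred within libraries gave 2 in macrophages, 1 in monocytes or dendritic cells, 7 in mural cells and 0 in other neurons. Equal numbers of cells gave 0 in cycling cells, 7 in macrophages, 13 in monocytes or dendritic cells and 0 in other neurons, and thinned counts 2 in cycling cells, 10 in mural cells and 0 in other neurons. No doublet removal gave 7 in macrophages and 0 in other neurons, doublets at the loading rate 442 in endothelial cells, 39 in mural cells and 0 in other neurons, and Leiden resolution 2 gave 0 in cycling cells and 0 in other neurons. Single clusters had 1 (cluster 3), 23 (cluster 6) and 1 (cluster 16) changed genes in fibroblasts, 6 (cluster 7) and 1 (cluster 18) in macrophages and 1 (cluster 17) and 25 (cluster 24) in endothelial cells, with fewer cells each.

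Leaving out 1 library gave 0 to 2 classes with a changed share, and the numbers of changed genes ranged from 0 to 190 in cycling cells, 191 to 491 in endothelial cells, 0 to 60 in erythroid cells, 0 to 31 in fibroblasts, 0 to 518 in the granule neuron lineage, 1 to 84 in macrophages, 11 to 199 in monocytes or dendritic cells, 6 to 270 in mural cells and 4 to 73 in other neurons. Called lists ranged from 4 to 13, 6 to 14, 7 to 14, 7 to 18, 9 to 18, 7 to 14, 6 to 11 and 4 to 7 in these classes without the endothelial one. Log2 changes of shares ranged from −2.10 to 0.18 (astroglia), −0.45 to 0.10 (granule neuron lineage), −0.97 to 0.17 (macrophages), −0.43 to 0.78 (mural cells), −0.63 to 0.94 (other neurons), −1.22 to 0.59 (choroid plexus), −0.72 to 0.79 (endothelial cells), −1.20 to 0.59 (erythroid cells), −0.60 to 0.68 (neutrophils), −0.19 to 0.13 (cycling cells) and −0.25 to 0.045 (unnamed cells). For lists that turned without a library, adjusted p ranged from 6.87e-05 to 0.960 (retinoic acid), 4.36e-06 to 0.960 (growth factors), 1.70e-31 to 0.0466 (cell cycle) and 7.31e-06 to 0.381 (haemoglobin) in erythroid cells. In the granule neuron lineage they ranged from 5.80e-06 to 0.904 (cholesterol synthesis), 2.06e-13 to 0.156 (blood-brain barrier), 1.01e-14 to 0.0152 (cell cycle) and 1.62e-05 to 0.419 (oxidative phosphorylation). In macrophages they ranged from 5.56e-28 to 0.745 (dissociation stress), 5.94e-08 to 0.997 (Hedgehog) and 3.12e-05 to 0.823 (granule cell differentiation), and in mural cells from 8.20e-06 to 0.827 (cell cycle). Log2 changes ranged from −0.36 to 0.13 for Cldn5 and −0.084 to 0.38 for Tspan12 in endothelial cells, and −0.50 to 0.53 for Gli1 and −0.40 to 0.26 for Ptch1 in the granule neuron lineage.

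With an estimated correlation 0 lists were called in each of the 9 classes, and fry called 0 in each but mural cells, where it called 1. No doublet removal gave 6 called lists in erythroid cells, the stricter filter 2 in erythroid cells, 7 in fibroblasts and 6 in mural cells, and doublets at the loading rate 1 in other neurons. Clusters 6, 11 and 14 had 7, 7 and 7 called lists, cluster 16 had 2, cluster 17 had 8 and cluster 18 had 6. Lists that turned had adjusted p of 0.408 (haemoglobin, cycling cells, centred values), 0.493 (cell cycle, granule neuron lineage, stricter filter) and 0.432 (granule cell differentiation, monocytes or dendritic cells, no doublet removal). With doublets at the loading rate these were 0.964 (retinoic acid) and 0.178 (haemoglobin) in erythroid cells, 0.890 (growth factors) in monocytes or dendritic cells and 2.77e-05 (cell cycle) in mural cells.

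Shares whose log2 change turned, all without a call, were neutrophils with TMM factors (0.0043), mural cells with neural, choroid plexus and erythroid cells left out of the total (−0.072), and choroid plexus (0.043) and other neurons (0.0095) with no doublet removal. The stricter filter turned cycling cells (0.11), endothelial cells (0.040), neutrophils (0.20), other neurons (0.26) and unnamed cells (0.21), and brought the share of fibroblasts to 19.2 ± 4.01% and 19.7 ± 1.80% (n = 2 each). Leiden resolution 2 turned cycling cells (0.0088) and other neurons (0.073), centred values cycling cells (0.0069), and doublets at the loading rate cycling cells (0.021), mast cells (−1.14), mural cells (−0.021) and neutrophils (0.93). Single genes turned only among those not called: Top2a in macrophages with no doublet removal (0.053), and Gli1 in the granule neuron lineage with the stricter filter (0.0019) and equal cells (0.17). Ndp over all barcodes of NdpKO replicate 1 was at 0.341 CPM, beyond the spread of the knockout libraries.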

Other observations

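The test for arterial genes within clusters was set up before its result was seen, while the test for genes near Ndp, in the form given, was chosen after it was seen, and the values of single clusters were computed only after the result for the whole class was seen.

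Among the endothelial clusters, cluster 13 had the most calls. In it, led by Cldn5, Clec14a and Kdr, 203 genes rose and 173 fell in the knockout, and peripheral and activated endothelial genes had a median log2 change of 1.14. In cluster 17, led by Eln, Fbln5 and Vwf, 0 rose and 1 fell, with 1 called by DESeq2. An unadjusted p under 0.05 was found for 405 of 10731 genes there, below the share of 0.05 that chance gives. Blood-brain barrier genes had a median of −0.61 in cluster 13 (adjusted p = 4.49e-22, and adjusted p = 0.349 with an estimated correlation) and −0.24 in cluster 17 (adjusted p = 1.58e-07, and adjusted p = 0.423 with an estimated correlation). Of the 329 genes called in cluster 13 and tested in both, 111 differed in their change between the clusters. In cluster 24 there were 9 genes that rose and 16 that fell. Lymphatic endothelial markers, summed, went from 137 and 134 CPM to 65.9 and 52.7 CPM in the endothelial class, a log2 change of −1.19 ± 0.16 SE. Ptgds, the prostaglandin D synthase that marks fibroblasts of cluster 3, stood in endothelial cells at 627 and 679 CPM in wild-type and 1695 and 1352 CPM in knockout libraries.

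Fibroblast clusters differed in how many genes changed. In cluster 6, led by Col15a1, Col4a1 and Col3a1, 19 genes rose and 4 fell, with 59 called by DESeq2. In cluster 3, led by Ptgds, Slc6a13 and Aldh1a2, 1 gene rose (39 by DESeq2). In cluster 11, led by Igfbp6, Mgp and Nppc, edgeR called 0 and DESeq2 15. Of 13466 genes tested in cluster 11, 637 had an unadjusted p under 0.05, near the share of 0.05 that chance gives. At Leiden resolution 2 a class with markers of the arachnoid barrier was named, which held 0.795 ± 0.310% of wild-type and 0.958 ± 0.418% of knockout cells (n = 2 each). Mfap4, a matrix gene and granule lineage marker here, was higher in both knockout libraries in cycling cells (log2 0.76), other neurons (1.91) and erythroid cells (0.82). Ostf1 was likewise higher in granule lineage (0.86) and cycling cells (1.01). Of these only Mfap4 in other neurons passed its test, which it did not without NdpWT replicate 1 (adjusted p = 0.104), and they were picked out after their values were seen.

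A larger part of arterial cells in knockout endothelium is a hypothesis for the higher arterial genes. Their median log2 change was 0.44 in the class, 0.27 within cluster 13 and −0.08 within cluster 17. A lower change within clusters than in the class is what the hypothesis predicts, but the change within cluster 13 remained above 0, so it stays open and may account for a part.

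Sequence from the donor strain of the knockout allele near Ndp could change genes next to it. Of 66 tested genes within 10 Mb of Ndp 2 changed in endothelial cells, where 1.54 would be by chance, against 292 of 12539 overall (one-sided Fisher's exact p = 0.457), with 9 of the 292 on chromosome X. Sequence linked to Ndp is thus argued against as the whole direct cause, and how far it reaches was not measured.

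Ttr, the main product of choroid plexus, avoided at dissection, was lower in both knockout libraries (218 and 555 against 61.5 and 21.6 CPM). Carry-over that differs with genotype was not tested. Over all barcodes Ndp was at 1.91 and 1.30 against 0.341 and 0.437 CPM.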
